A study of Mus musculus with 29 samples.

How the data were processed

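The data came from islets of male C57BL/6 mice of 8 or 52 weeks, fed a standard or a high-fat diet for 1 week, with 14 RNA libraries and 15 methylation libraries. The RNA was taken up in Trizol and made into stranded libraries from polyadenylated RNA. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.4.2a, counted with featureCounts 1.4.3, and described with Picard 1.83, and the diets were compared within each age with DESeq2. For methylation, the notes name Trimmomatic, BSMAP and bedtools.

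The authors deposited raw read counts per Ensembl gene, in 1 table per age, which were used for all RNA tests. The authors also deposited kallisto estimated counts (expected counts) per transcript, which served here only to read the unit of the totals. Quality tables deposited by the authors give percent of reads, the number of reads per library, and ratios of coverage at the ends of transcripts. The authors' deposited DESeq2 tables give log2 fold changes with their standard errors, p-values with adjusted p-values, and mean normalised counts. For each CpG site the deposited methylation files give the read coverage in counts and the percent of reads with C and with T. Samples were grouped by age and diet as the labels give them. The gene table holds 45232 genes, 207 of them with a symbol shared with another gene, so genes were followed by Ensembl identifier.

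RNA depth was 68395276 to 79652561 counts per library, with 1.39 to 1.69 counts per read pair, so that both mates of a pair were often counted. Duplicate reads were 44.4 to 52.5%, and reads without molecular identifiers are not independent molecules. The p-values measure the spread between samples, not the counting error. Strand agreement was 99.6 to 99.8%, but the strand setting of the counting is not stated, so genes that overlap on opposite strands may share counts. The same holds for near-identical genes, such as Hspa1a and Hspa1b, Ins1 and Ins2, and immunoglobulin genes. Within each group, every pair of libraries was compared by a chi-square per gene among highly counted genes. In old islets, 1 pair per diet had a scaled median of 2.76 to 2.88, against 6.51 to 18.2 for the other pairs. The scaling makes this median 1 if every count were independent. Mates counted together and duplicate reads raise it above 1, so it does not measure how far the libraries of a pair differ beyond counting error. Each pair under a limit of 3 was summed to 1 sample, which leaves 12 RNA samples. The mean counts in the authors' deposited table for old islets match replicates 1 to 3 of each diet: 0 of 12999 genes differ by more than 0.1%, whereas with all 8 libraries 12340 do.

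Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalisation, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjusted p-values and a threshold of 0.05. The diet was tested within each age from the libraries of that age, and the interaction and the age difference on the standard diet from all RNA samples. Tests were two-sided. Before the data were examined, 34 gene lists with 586 matched members were fixed, together with the comparisons, tests and most alternatives. Of these lists, 33 had at least 3 tested members in every comparison and were tested with camera (limma 3.58.1, preset correlation 0.01, on voom log2 CPM), with an estimated correlation and fry beside it. Members of a list were also adjusted over the list alone. Levels of a list are means of log2 CPM, with about 0.5 counts, not 0.5 CPM, added to each gene in a library. DESeq2 1.42.0 was run as an alternative.

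Named genes followed a rule: up to 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 2 CPM in the higher group and no overlap between groups (8 and 8 for age, and no overlap condition for the interaction). The rule added up to 4 members of each list with the smallest p, and always Myc, Mki67, Ccnd2, Cdkn2a, Ins1, Ins2, Gcg and Ctrb1. Named sites and promoters are those past the threshold with the largest differences, or else those with the smallest p.

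Methylation was tested per site with a quasi-binomial model of methylated and unmethylated reads, with a dispersion moderated by empirical Bayes and held at 1 or above, an F test and adjustment over all sites tested. Sites needed a coverage of at least 10 in every library compared. Promoters ran from 1500 bp upstream to 500 bp downstream of the gene start and needed at least 3 such sites. Means per library were compared by exact two-sided permutation tests. Reads over CpG sites numbered 488262 to 799617 per library, and 2403 to 7553 sites per library had a coverage of at least 10, so most of the sites listed could not be tested.

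The model fits were tested on simulated counts, drawn anew rather than taken from the libraries, with changes put in. For RNA they were drawn for each gene on its own, from its mean level and spread in the data. Samples rich in other tissue and genes that vary together are thus not part of the simulation, and recovery in the real data may be lower. For the diet in young islets, edgeR recovered 40.3% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 93.9% of those changed 4-fold, and in old islets 53.7%, 73.1% and 93.9%. Of the calls on simulated data, 7.48% in young and 13.0% in old islets were genes that had not been changed. The site model recovered 179 of 200 sites shifted by 2 on the logit scale and 45 of 200 shifted by 1, each shifted towards intermediate levels. In these runs 12 and 4 unchanged sites were called. The counts were drawn at the coverage of the young libraries, with a spread that was set rather than measured. Unchanged sites had an unadjusted p under 0.05 in 6.51 to 6.83% of cases, against 29 of 1137 real young sites. The recovered shares may therefore not carry over to the real sites. Alternatives covered normalisation, filters, tools, coverage, promoter windows, covariates, a replicate block and leaving out each sample in turn, and others were chosen after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The kallisto counts were not used for tests, as no map from transcripts to genes was at hand, and CpGs in the Myc binding motif were not analysed here, as no genome sequence was.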

Results

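RNA was sequenced from pancreatic islets of male C57BL/6 mice, an inbred strain, and the mice were 8 or 52 weeks of age. They ate either a standard diet, in which fat gave 13.1% of kcal, or a high-fat diet, in which it gave 41%, for 1 week. DNA methylation was measured in islets of the same 4 kinds of mice by bisulfite sequencing of chosen parts of the genome. The series title concerns Myc, a transcription factor that drives cell growth and division, and the replication of beta cells. Myc RNA is therefore given for the diet at each age and the interaction, and cell cycle genes for each RNA comparison. The RNA libraries numbered 3 per diet in young mice and 4 per diet in old mice, and total gene counts ranged from 68395276 to 79652561 per library. In old islets, standard-diet libraries 2 and 4 were almost the same in their counts, and so were high-fat libraries 1 and 4. Across immunoglobulin V genes, whose use differs from animal to animal, Spearman correlations across genes were 0.952 to 0.957 within these pairs and -0.530 to 0.450 in the other pairs of libraries from 1 group. Each of these pairs was summed and counted as 1 sample, called sample 2-4 and sample 1-4, which left 3 samples in every RNA group. The methylation libraries numbered 4 per group, except 3 from old mice on the high-fat diet, and listed 344200 to 556009 CpG sites each at a median coverage of 1 read.

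In young islets, the first question was what 1 week of high-fat diet does to the cell division program. RNA of genes for the G2 and M phases was higher on the high-fat diet: all 32 measured members of that list were higher, with a median log2 change of +1.13. Mki67, whose protein marks dividing cells, had 11.7 ± 2.54 CPM (SD, n = 3) on the standard diet and 23.6 ± 6.83 CPM (SD, n = 3) on the high-fat diet. Its log2 change was +1.01 (SE 0.24), with an adjusted p of 0.142 by edgeR and 2.10e-04 by DESeq2. Cdk1, the kinase that drives entry into mitosis, differed by +1.32 (SE 0.19), and Ccna2, the cyclin A2 gene, by +1.18 (SE 0.16), with adjusted p of 0.092 and 0.091. Hmmr, a spindle gene, differed by +1.37 (SE 0.16) with an adjusted p of 0.0819, and Cenpf, a kinetochore gene, by +1.44 (SE 0.22) with an adjusted p of 0.0995. Of the 32 genes, 29 rose when adjusted over the list alone, and 0 passed when adjusted over all 16724 genes tested by edgeR. The list as a group rose (camera adjusted p = 5.78e-26, against adjusted p = 0.465 with an estimated correlation). Markers of Schwann cells, the glia of nerves, were also higher, with a median log2 change of +0.82, and 8 of their 9 tested genes were higher.

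**Figure D1:**
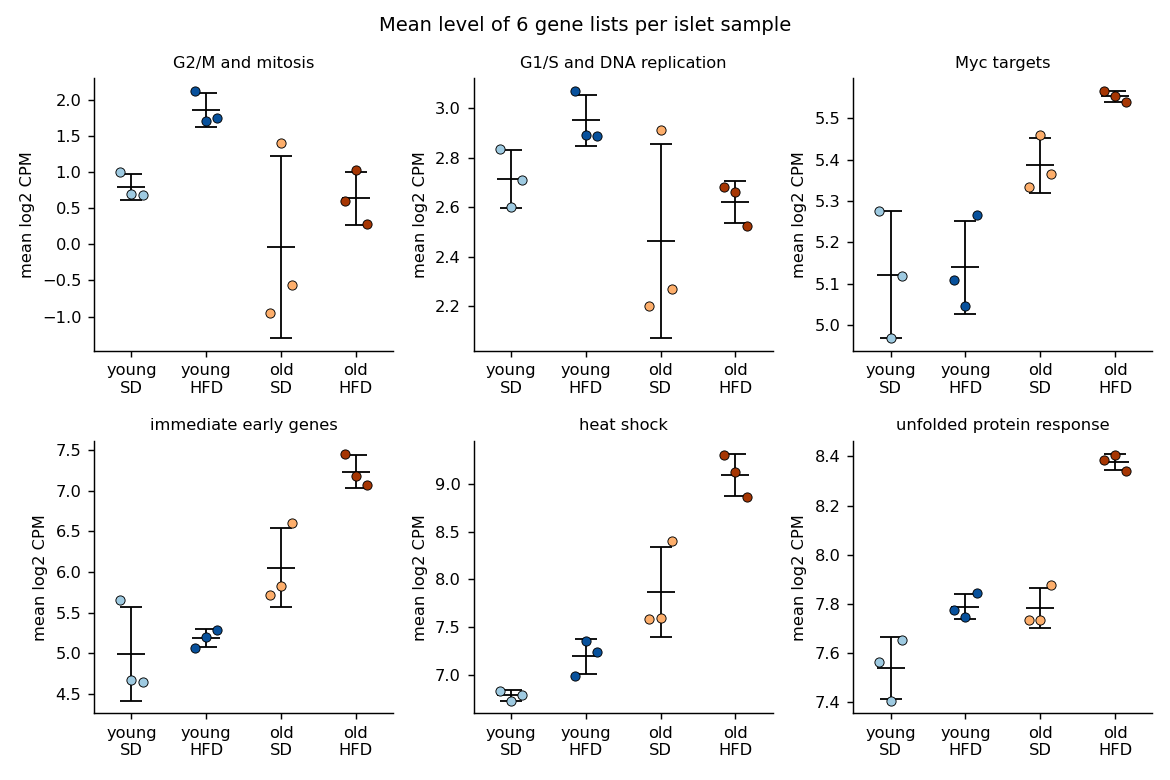
Mean log2 CPM of 6 gene lists in each of the 12 RNA samples, by age and diet; points are samples and bars show the mean with 1 SD (n = 3 per group). For the G2/M list the young samples averaged 1.85 on the high-fat diet and 0.79 on the standard diet, with no overlap. No overlap by diet was seen for 12 of 34 lists in young islets.

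Across all genes, 5 passed in young islets by edgeR. H2afx (ENSMUSG00000049932.3, mm10 chromosome 9, 44334694 to 44336077), which encodes a histone H2A variant that marks DNA breaks, rose by 0.72 log2 (SE 0.06), from 11.7 ± 0.297 to 19.3 ± 0.972 CPM (SD, n = 3). Usp51 (ENSMUSG00000067215.5, chromosome X, 153006469 to 153009416), a ubiquitin protease gene, rose by 0.75 (SE 0.07), and E530001K10Rik (ENSMUSG00000075020.5, chromosome 2, 94251879 to 94264758) rose by 0.68 (SE 0.05). Cpm (ENSMUSG00000020183.8, chromosome 10, 117629500 to 117687352), a carboxypeptidase gene, fell by 0.85 (SE 0.07), and Ighg2b (ENSMUSG00000076613.3, chromosome 12, 113302965 to 113307933), an antibody heavy chain gene of plasma cells, fell by 4.78 (SE 0.38). All 5 had an adjusted p of 0.0269. Myc itself had 14.7 ± 5.13 CPM (SD, n = 3) on the standard diet and 16.1 ± 3.07 CPM (SD, n = 3) on the high-fat diet, a log2 change of +0.11 (SE 0.25) with an adjusted p of 0.851. In the authors' deposited table the log2 change of Myc in young islets was +0.08 (adjusted p 0.871). Without any 1 of the 6 libraries edgeR called 0 genes, with 1750 to 2707 genes at an unadjusted p under 0.05. With all libraries 2858 genes had such a p, and DESeq2 called 707 genes (371 higher, 336 lower). The authors' deposited table, from the same libraries, lists 617 genes past an adjusted p of 0.05 (364 higher, 253 lower), of which edgeR called 5. All 616 of these that were tested here had the same sign, which is no independent support because the libraries are shared. The groups did not overlap at 3975 genes (23.8%), where chance gives 10%.

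Beside the G2/M list, 13 of the 33 tested lists changed in young islets by camera, and fry called 0 lists. Genes of the unfolded protein response, which handles misfolded secretory proteins, rose as a group: 22 of 24 were higher, 6 rose when adjusted over the list alone, and the adjusted p was 2.74e-07 (adjusted p = 0.497 with an estimated correlation). Among them, Herpud1, a gene for degradation of proteins from the endoplasmic reticulum, differed by +0.74 log2 (SE 0.09, adjusted p 0.0819). All 8 heat shock genes were higher, and 6 rose when adjusted over the list alone (list adjusted p 3.24e-06, and adjusted p = 0.465 with an estimated correlation). Of 24 genes for ribosome assembly, 21 were higher and 5 rose over the list alone (list adjusted p 6.83e-06, and adjusted p = 0.465 with an estimated correlation). Srm, the spermidine synthase gene and a Myc target, differed by +0.60 (SE 0.09, adjusted p 0.0995), and 24 of 32 Myc targets were higher with 1 risen over the list alone (list adjusted p 0.00109, and adjusted p = 0.591 with an estimated correlation). Genes of G1/S and DNA replication were higher in 30 of 35 cases, with 0 risen over the list alone by edgeR (list adjusted p 4.48e-06, and adjusted p = 0.497 with an estimated correlation). All 19 nuclear genes of oxidative phosphorylation and 11 of 12 mitochondrially encoded genes were higher, with 1 risen over the list alone in each, and both lists had an adjusted p of 6.83e-06 (adjusted p = 0.497 with an estimated correlation for both). Of 19 secretory granule genes, 15 were higher and 1 rose over the list alone (list adjusted p 0.00744, and adjusted p = 0.497 with an estimated correlation). That list lost its call without young high-fat library 1 (adjusted p 0.0607) or with the lymphocyte level as a covariate (adjusted p 0.139), a covariate chosen after seeing the data. Immediate early genes, the first to respond to stimulation or stress, were higher in 14 of 21 cases with 0 risen over the list alone (list adjusted p 0.00365, and adjusted p = 0.724 with an estimated correlation), and the list lost its call without standard-diet library 2 (adjusted p 0.0963) or 3 (adjusted p 0.155). Without such a call for the list, 4 cell cycle inhibitors rose and 1 fell when adjusted over the list alone. Cdkn1a, which encodes the inhibitor p21, differed by +0.76 (SE 0.14, adjusted p 0.109). Among 22 beta cell identity genes, 4 rose and 6 fell over the list alone. Pdx1, a transcription factor that keeps beta cell identity, differed by -0.48 (SE 0.07, adjusted p 0.091), and G6pc2, a glucose-6-phosphatase of beta cells, by +0.63 (SE 0.10, adjusted p 0.0995). Cpt1a, which brings fatty acids into mitochondria, differed by +0.51 (SE 0.06, adjusted p 0.0819).

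Markers of other cells moved with the diet in young islets. All 13 lymphocyte genes were lower on the high-fat diet, with a median log2 change of -3.29, and 10 fell when adjusted over the list alone (list adjusted p 4.69e-04, and adjusted p = 0.709 with an estimated correlation). Standard-diet library 1 held the most lymphocyte RNA, at a mean log2 CPM of 2.96, against -0.58 and -0.09 in the other libraries of its group, and without it the median log2 change of the lymphocyte genes was -0.90. All 17 macrophage genes were lower, with 1 fallen over the list alone (list adjusted p 0.00119, and adjusted p = 0.724 with an estimated correlation). The macrophage change rested largely on the same library: the median log2 change was -0.86, and without that library it was -0.18 with 12 of 17 genes lower (adjusted p 0.0195). With the lymphocyte level as a covariate, chosen after seeing the data, the macrophage list turned to higher (median +0.19, adjusted p 0.00442, and adjusted p = 0.572 with an estimated correlation). Of 23 acinar genes, which encode digestive enzymes of the exocrine pancreas, 22 were lower with 1 risen over the list alone (list adjusted p 0.00537, and adjusted p = 0.802 with an estimated correlation). High-fat library 1 had an acinar level of 5.55 mean log2 CPM, and the other young libraries had 8.62 to 9.72. Without that library the acinar list was turned in direction, with an adjusted p of 0.888, and its adjusted p was 0.072 without standard-diet library 3 and 0.875 with the lymphocyte covariate. Of the 9 Schwann cell genes, 5 rose and 1 fell over the list alone (list adjusted p 6.22e-04, and adjusted p = 0.497 with an estimated correlation). S100b, a glial calcium-binding protein gene, differed by +1.61 (SE 0.32, adjusted p 0.114). For the islet hormones, Ins1, an insulin gene, differed by +0.28 (SE 0.08, adjusted p 0.196), and Gcg, the glucagon gene, by -0.41 (adjusted p 0.417).

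**Figure D2:**
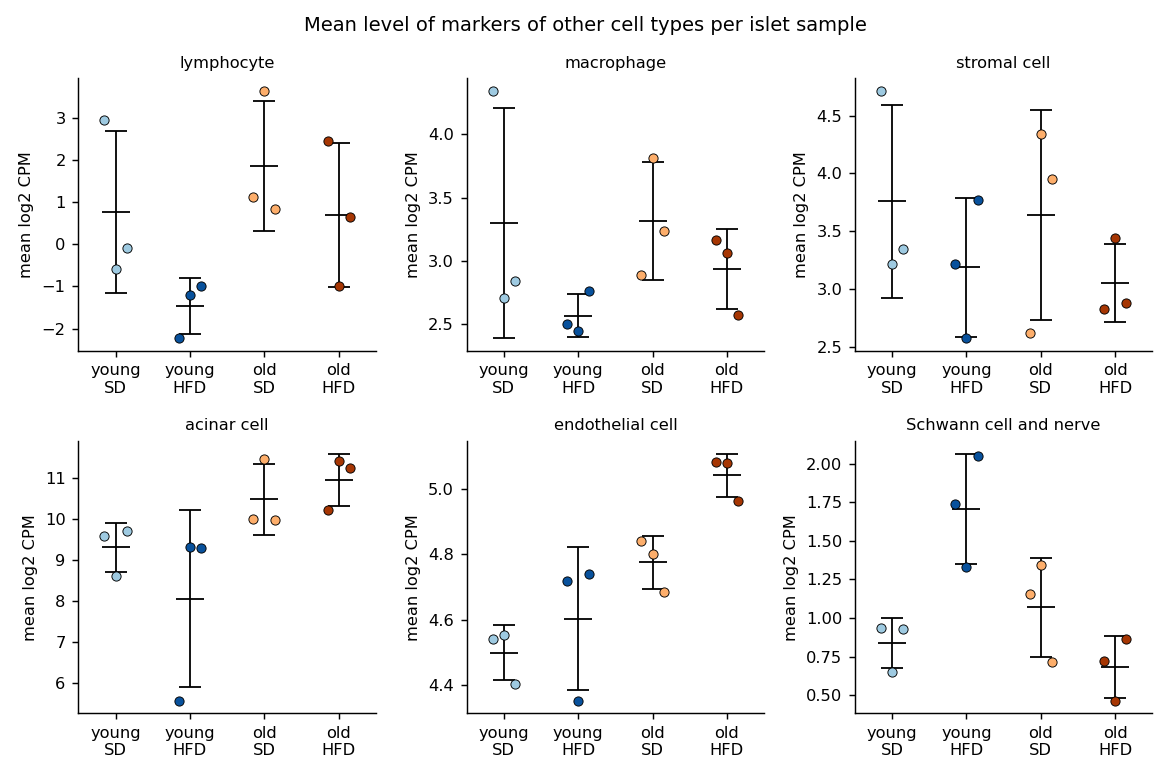
Mean log2 CPM of 6 lists of markers of other cell types in each of the 12 RNA samples; points are samples and bars show the mean with 1 SD (n = 3 per group). Lymphocyte markers were highest in old standard-diet sample 2-4 at 3.64, and acinar markers were lowest in young high-fat library 1 at 5.55.

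In old islets, 1 week of high-fat diet went with higher RNA of Myc, of immediate early genes and of genes for misfolded proteins. Myc (ENSMUSG00000022346.11, mm10 chromosome 15, 61985341 to 61990374) rose by 0.93 log2 (SE 0.17, adjusted p 0.0348), from 13.4 ± 3.41 to 25.8 ± 2.02 CPM (SD, n = 3). Mki67 (ENSMUSG00000031004.7, chromosome 7, 135689788 to 135716379) had 8.38 ± 9.93 CPM (SD, n = 3) on the standard diet and 6.99 ± 2.04 CPM (SD, n = 3) on the high-fat diet, a log2 change of -0.27 (SE 0.78) with an adjusted p of 0.877. Without the samples richest in lymphocyte RNA, standard-diet sample 2-4 and high-fat sample 1-4, an alternative chosen after seeing the data, the log2 change of Mki67 turned to +1.17 and passed (adjusted p 0.0380). Standard-diet sample 2-4 was the highest old sample in G2/M genes, and the rest of its group were the lowest, at a mean log2 CPM of -0.95 and -0.57. The G2/M list had 23 of 32 genes higher with 0 past the threshold by edgeR (list adjusted p 0.0611, and adjusted p = 0.832 with an estimated correlation). By camera the list passed as higher without sample 2-4 (adjusted p 7.89e-14, and adjusted p = 0.529 with an estimated correlation), without high-fat library 3 (adjusted p 0.0251, and adjusted p = 0.840 with an estimated correlation) and with a block for replicates (adjusted p 0.0159). In alternatives chosen after seeing the data it also passed without the libraries numbered 4 (adjusted p 0.00251), without both lymphocyte-rich samples (4.42e-13), with all libraries in 1 fit (0.0490) and with the lymphocyte level as a covariate (0.0245). Without standard-diet library 1 only 12 of its 32 genes were higher, and 13 without standard-diet library 3. By an estimated correlation or fry it passed in 0 of these. In the authors' deposited table Myc in old islets had a log2 change of +0.81 (adjusted p 1.09e-07) and Mki67 one of -0.03 (adjusted p 0.929).

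All 21 immediate early genes were higher in old islets on the high-fat diet, with a median log2 change of +1.01, and 10 rose (20 when adjusted over the list alone). Fosb (ENSMUSG00000003545.2, chromosome 7, 19302721 to 19310045), an AP-1 subunit gene, rose by 1.86 (SE 0.39, adjusted p 0.0456), Klf6 by 1.64 (SE 0.24) and Btg2, a brake on proliferation, by 1.06 (SE 0.15). The list rose with an adjusted p of 2.56e-15 (adjusted p = 0.404 with an estimated correlation). All 24 unfolded protein response genes were higher, and 10 rose (18 when adjusted over the list alone), among them Herpud1 by 1.26 (SE 0.14, adjusted p 0.0216), Manf by 0.78 and Sdf2l1 by 0.61. That list had an adjusted p of 2.56e-15 by camera, 0.00439 by fry, and adjusted p = 0.141 with an estimated correlation. Of 8 heat shock genes, 4 rose (8 over the list alone), with Bag3, a co-chaperone gene, risen by 1.92 (SE 0.35, adjusted p 0.035). Hspa1a rose by 1.27 and Hspa1b by 1.17, but these genes are nearly identical in sequence, so reads cannot be assigned to either with certainty. The heat shock list had an adjusted p of 5.90e-07 (adjusted p = 0.404 with an estimated correlation). Myc targets rose as a list, with 3 genes risen (8 over the list alone), 23 of 32 higher and a median log2 change of +0.07 (adjusted p 0.0234, fry 0.00779, and adjusted p = 0.404 with an estimated correlation). With the acinar level as a covariate, for lists an alternative chosen after seeing the data, the Myc target list lost its call by camera (adjusted p 0.0549, fry 0.0186). Hspd1, a mitochondrial chaperone gene in that list, rose by 0.64 (SE 0.13, adjusted p 0.0448). Of 12 cell cycle inhibitors, 2 rose (3 over the list alone), Cdkn1a by 1.04 (SE 0.17, adjusted p 0.0293) and Cdkn2b, which encodes p15, by 0.69 (SE 0.15, adjusted p 0.0499). E2f1, a transcription factor of S phase entry, rose by 0.54 (SE 0.08, adjusted p 0.0259), and 2 of 35 genes of G1/S and DNA replication rose (list adjusted p 0.182).

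Of 19 genes that make fatty acids, 14 were lower in old islets on the high-fat diet, 3 fell and 1 rose (6 and 1 when adjusted over the list alone). Fasn (ENSMUSG00000025153.8, chromosome 11, 120805940 to 120824178), the fatty acid synthase gene, fell by 0.79 log2 (SE 0.08, adjusted p 0.0216), to 55.4 ± 4.56 CPM (SD, n = 3) from 95.0 CPM. Acly, which makes the acetyl-CoA for it, fell by 0.65 (SE 0.10, adjusted p 0.0277), and Acaca, the acetyl-CoA carboxylase gene, fell by 0.46 (adjusted p 0.0418). Lpin1, a gene of triglyceride synthesis, rose by 0.57 (adjusted p 0.0216). The list as a group passed (adjusted p 0.0175, and adjusted p = 0.404 with an estimated correlation), but not without standard-diet sample 2-4 (adjusted p 0.0845) or without both lymphocyte-rich samples (adjusted p 0.345). Of 25 fatty acid oxidation genes, 20 were higher and 2 rose (2 over the list alone), Cpt1a by 0.32 and Acadvl by 0.24 (list adjusted p 0.00428, fry 0.0286, and adjusted p = 0.404 with an estimated correlation). Mafa (ENSMUSG00000047591.4, chromosome 15, 75746843 to 75747922), a transcription factor of mature beta cells, fell by 0.71 (SE 0.07, adjusted p 0.0216), from 43.9 ± 3.68 to 27.0 ± 1.56 CPM (SD, n = 3), and it was the only 1 of 22 beta cell identity genes past the threshold in edgeR (list adjusted p 0.912). Ins1 differed by +0.31 (adjusted p 0.548), and Ins1 and Ins2 share much of their sequence. Vip (ENSMUSG00000019772.4, chromosome 10, 5639218 to 5647614), a neuropeptide gene, fell by 2.16 (SE 0.28, adjusted p 0.0216), from 25.2 ± 5.30 to 5.61 ± 2.12 CPM (SD, n = 3). Irs2, which carries the insulin signal, rose by 1.84 (SE 0.33, adjusted p 0.035).

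**Figure D3:**
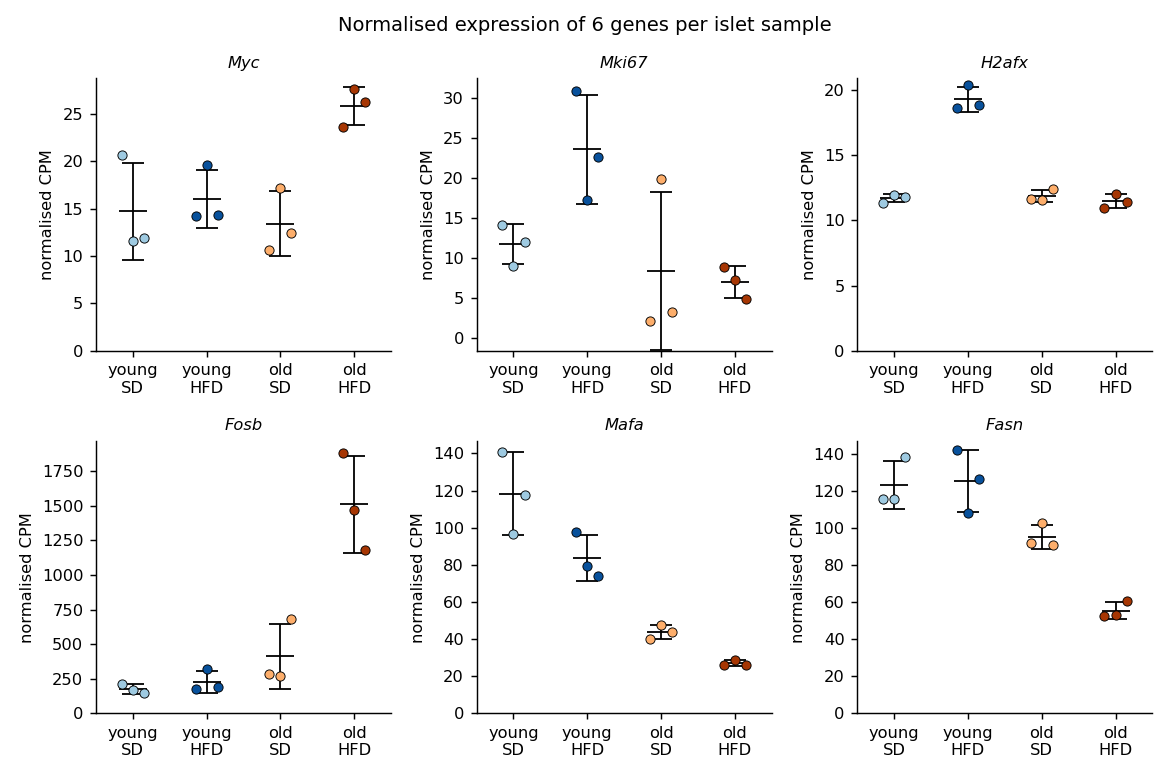
Normalised CPM of 6 genes in each of the 12 RNA samples; points are samples and bars show the mean with 1 SD (n = 3 per group). The Myc mean was 25.8 CPM in old islets on the high-fat diet and 13.4 CPM on the standard diet, and 1 old standard-diet sample held most of the Mki67 RNA of its group.

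Genes of vessels and inflammation were also higher in old islets on the high-fat diet. Selp (ENSMUSG00000026580.13, chromosome 1, 164115264 to 164150026), the gene of the adhesion protein P-selectin, rose by 2.84 log2 (SE 0.25, adjusted p 0.0216), and Sele, the E-selectin gene, by 2.54 (SE 0.46, adjusted p 0.0351). All 14 endothelial genes were higher, with 0 risen over all genes by edgeR and 7 over the list alone (list adjusted p 2.82e-05, and adjusted p = 0.404 with an estimated correlation). Of 13 inflammation genes, 12 were higher and 1, Nfkbia, rose by 0.62 (list adjusted p 0.00428, and adjusted p = 0.778 with an estimated correlation), but the list lost its call without standard-diet library 1 (adjusted p 0.074) or sample 1-4 (adjusted p 0.0872). Interferon response genes were higher in 17 of 23 cases, and 2 rose (4 over the list alone): Rsad2 by 1.14 and Ifit1 by 1.12. The interferon list (adjusted p 0.02, and adjusted p = 0.832 with an estimated correlation) lost its call without standard-diet library 1 (0.17) or 3 (0.196) or high-fat sample 1-4 (0.101), each an adjusted p. All 5 red blood cell genes were higher and rose over the list alone (list adjusted p 0.00128, and adjusted p = 0.404 with an estimated correlation). All 23 acinar genes were higher with 0 past the threshold by edgeR, with a median log2 change of +0.32, and +0.09 to +1.04 without each sample in turn (list adjusted p 0.0229, and adjusted p = 0.832 with an estimated correlation), but the list lost its call without standard-diet library 1 (adjusted p 0.373) or 3 (adjusted p 0.386) or high-fat library 2 (adjusted p 0.201) or 3 (adjusted p 0.132). Macrophage genes were lower in 16 of 17 cases (list adjusted p 0.0234, and adjusted p = 0.832 with an estimated correlation), and that call ended without standard-diet sample 2-4 (adjusted p 0.346) or high-fat library 3 (adjusted p 0.145). Stromal genes were lower in 13 of 14 cases (list adjusted p 0.0281, and adjusted p = 0.778 with an estimated correlation), and that call ended without standard-diet sample 2-4 (adjusted p 0.273) or high-fat sample 1-4 (adjusted p 0.104). In alternatives chosen after seeing the data, further calls ended, each given by its adjusted p. With the acinar covariate the interferon list had 0.104, and with the lymphocyte covariate the macrophage list had 0.0931 and the stromal list 0.0515. With all libraries in 1 fit the acinar list had 0.229, the macrophage list 0.120 and the stromal list 0.0577. The acinar list had 0.908 with near-identical libraries apart, and the stromal list had 0.0558 without the libraries numbered 4 and 0.653 without both lymphocyte-rich samples.

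In total 758 of 16929 genes passed in old islets by edgeR, 359 higher and 399 lower on the high-fat diet. By camera 13 lists changed, 10 higher and 3 lower, and by fry 4, and the mean level of the list set all samples of the diets apart in 7 of 34 lists, where the smallest exact permutation p for 3 against 3 samples is 0.1. The groups did not overlap at 5093 genes (30.1%), where chance gives 10%. The authors' deposited table, whose mean counts match libraries 1 to 3 of each diet, lists 1880 genes (964 higher, 916 lower), of which edgeR called 752. All 1880 had the same sign here, which is no independent support because the libraries are shared. Over all genes, edgeR called 0 without standard-diet library 1, high-fat sample 1-4, high-fat library 2 or high-fat library 3. It called 222 without standard-diet library 3 and 468 without standard-diet sample 2-4, and DESeq2 called 2006 with all samples. For Myc the call ended when any 1 sample except standard-diet sample 2-4 was left out, with adjusted p up to 0.121.

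The interaction asks whether the diet acted differently at the 2 ages, and 36 of 17644 genes passed it by edgeR, 30 with a more positive and 6 with a more negative diet change in old islets. Ppp1r3c (ENSMUSG00000067279.2, chromosome 19, 36731737 to 36736653), which directs a phosphatase to glycogen, had the log2 changes -1.17 in young and +1.26 in old islets, an interaction of +2.43 (SE 0.31, adjusted p 0.033). Dusp8 (ENSMUSG00000037887.8), a phosphatase gene of stress kinases, had changes of -0.31 and +1.91 (interaction +2.21, adjusted p 0.0477), and Nfil3 (ENSMUSG00000056749.7), a transcription factor of the clock, had -0.27 and +1.27 (interaction +1.54, adjusted p 0.0346). H2afx had changes of +0.72 and -0.06 (interaction -0.78, SE 0.09, adjusted p 0.0276). Hand2 (ENSMUSG00000038193.3, chromosome 8, 57320983 to 57324517), a transcription factor of neural crest cells, had changes of +1.62 and -0.94 (interaction -2.56, SE 0.36, adjusted p 0.0388). The diet change of Myc was not shown to differ between ages (interaction +0.82, SE 0.33, adjusted p 0.335), nor that of Mki67 (interaction -1.29, SE 0.91, adjusted p 0.636).

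Among gene groups, 12 lists passed the interaction by camera, 8 more positive and 4 more negative in old islets, and 0 by fry. Immediate early genes (median interaction +0.85, adjusted p 9.55e-10, and adjusted p = 0.547 with an estimated correlation), heat shock genes (+0.74, adjusted p 2.57e-05, and adjusted p = 0.547 with an estimated correlation) and unfolded protein response genes (+0.24, adjusted p 3.28e-06, and adjusted p = 0.490 with an estimated correlation) had a more positive diet change in old islets. Without young standard-diet library 1 the median for immediate early genes was +0.51. Ribosome biogenesis genes had a more negative one (-0.22, adjusted p 1.04e-07, and adjusted p = 0.316 with an estimated correlation). All 32 G2/M genes had a more negative diet change in old islets (median interaction -0.84, adjusted p 0.00133, and adjusted p = 0.861 with an estimated correlation). Without old standard-diet sample 2-4 the G2/M interaction was turned in direction, with an adjusted p of 0.142, and without the libraries numbered 4 its adjusted p was 0.0673. Markers of other cells moved with it too: Schwann cell genes were more negative (-1.71, adjusted p 6.37e-05, and adjusted p = 0.490 with an estimated correlation) and acinar genes more positive (+0.88, adjusted p 4.92e-04, and adjusted p = 0.831 with an estimated correlation), the acinar call ending without young high-fat library 1 (median +0.34, adjusted p 0.0939), while the median was +1.61 without old standard-diet sample 2-4. The gene count by edgeR was 0 without young standard-diet library 3, young high-fat library 1 or 3, old standard-diet library 1 or sample 2-4, or old high-fat library 2, with 2198 genes at an unadjusted p under 0.05 with all samples. It was 1 without young standard-diet library 2 or young high-fat library 2, 10 without young standard-diet library 1, 13 without old high-fat sample 1-4 and 69 without old high-fat library 3, and DESeq2 called 448 with all samples.

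Genes called in young islets were then followed in old ones. Of the 3 that rose in young islets, 2 had the same sign in old islets (fry p 0.454), and of the 2 that fell, both did (fry p 0.0598). Of the 371 genes that DESeq2 called higher in young islets, 366 could be followed in old islets. Among these 366, 323 were higher in old islets too (fry p 0.00149). Of the 336 it called lower, 329 could be followed, and 237 of these were lower (fry p 0.0811). Across 16325 genes the diet changes at the 2 ages had a Spearman correlation of 0.316 across genes, which are not independent replicates. Of 753 genes called in old islets and tested in both, 609 (80.9%) had the same sign in young islets, against 63.7% of all genes.

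With age on the standard diet, beta cell identity genes were lower and immediate early and heat shock genes were higher in old islets. Of 22 beta cell identity genes, 10 fell and 3 rose, with Mafa fallen by 1.45 log2 (SE 0.14, adjusted p 4.08e-05) and Nkx2-2, a transcription factor of beta cells, by 0.93 (SE 0.07, adjusted p 1.10e-05). The list fell (adjusted p 0.00277, and adjusted p = 0.477 with an estimated correlation). Igf2bp2, an RNA-binding protein gene, fell by 3.49 (SE 0.27, adjusted p 1.19e-05). The cell cycle genes E2f1, fallen by 1.20 (SE 0.09), and Ccnd1, the cyclin D1 gene, fallen by 0.91 (SE 0.09), were lower in old islets, while Cdkn2a, a senescence gene that encodes p16, rose by 1.44 (SE 0.33, adjusted p 0.00681). The level of Myc targets went from 5.12 to 5.39 mean log2 CPM. That of the list of Myc and related factors went from 4.12 to 3.79, each with no overlap between the groups, as in 18 of the 34 lists by age. By camera the list of Myc and related factors lost its call without young standard-diet library 2 (adjusted p 0.0536) or 3 (adjusted p 0.0551). It also lost its call without old standard-diet library 1 (adjusted p 0.0542). Gcg fell by 1.08 (adjusted p 0.00904) and Sst, the somatostatin gene, by 1.19 (adjusted p 1.76e-04). Of 21 immediate early genes, 12 rose, among them Fos by 1.32 and Atf3 by 2.32 (list adjusted p 5.43e-06, and adjusted p = 0.477 with an estimated correlation), and 7 of 8 heat shock genes rose. Of 19 oxidative phosphorylation genes 13 rose and 1 fell, with Cox5a risen by 0.95 (list adjusted p 5.43e-06, and adjusted p = 0.428 with an estimated correlation). Of 32 G2/M genes 1, Anln, fell (adjusted p 0.00327), with 0 risen (list adjusted p 0.0487, and adjusted p = 0.839 with an estimated correlation). The G2/M call ended without young standard-diet library 1 (adjusted p 0.114) or 2 (adjusted p 0.0536) or old standard-diet library 1 (adjusted p 0.589) or 3 (adjusted p 0.277). The G2/M level differed by -0.83 mean log2 CPM between ages, by -1.55 without old standard-diet sample 2-4 and by -0.37 without old standard-diet library 1. Markers of other cells moved with age as well. All 23 acinar genes were higher in old islets with 0 past the threshold by edgeR, with a median log2 change of +1.30 (list adjusted p 0.0277, and adjusted p = 0.833 with an estimated correlation), and the acinar level went from 9.31 ± 0.602 to 10.5 ± 0.859 mean log2 CPM (SD, n = 3). Without old standard-diet sample 2-4 the difference in acinar level was 0.67 in place of 1.17 and the list lost its call (adjusted p 0.247), as it did without young standard-diet library 2 (adjusted p 0.106). Ductal genes went from 2.18 to 2.98 and endothelial genes from 4.50 to 4.78 mean log2 CPM, each with no overlap between the groups, though neither list passed by camera (adjusted p 0.349 and 0.192). By camera 14 lists passed between ages, a test chosen after seeing the data, against 0 with an estimated correlation and 15 by fry, of which 11 were shared. Of these 14, 10 passed without young standard-diet library 2, 11 without young standard-diet library 3, 11 without old standard-diet sample 2-4, 11 without both lymphocyte-rich samples and 11 with the lymphocyte covariate. By edgeR 5378 genes passed (2435 higher, 2943 lower), and the groups did not overlap at 7499 genes (42.5%), where chance gives 10%. Young and old libraries were processed into separate tables and mapped uniquely for 86.8 to 90.5% and 75.0 to 83.7% of reads, so age and batch cannot be told apart here.

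In the methylation data, no change with diet was detectable at single sites at this depth. Of 1137 sites covered by at least 10 reads in every young library, 0 passed in the quasi-binomial model, with 29 at an unadjusted p under 0.05 and 35 by limma, which also called 0. In old islets 0 of 767 sites passed (19 at such a p, and 34 by limma), and between ages 0 of 802 did (38 at such a p, and 44 by limma). The old site with the smallest p lay on chromosome 11 at 99026586 upstream of Top2a, a topoisomerase gene of dividing cells. Its methylation level was 69.2% ± 14.03 (SD, n = 4) on the standard diet and 95.4% ± 4.09 (SD, n = 3) on the high-fat diet, at a coverage of 10 to 23 reads, with an adjusted p of 0.994. Mean methylation over the 632 sites covered at least 10 times in all 15 libraries was 78.2% ± 0.513 (SD, n = 4) and 78.2% ± 0.366 (SD, n = 4) in young islets on the standard and high-fat diet (exact two-sided permutation p 0.971). It was 78.5% ± 0.410 (SD, n = 4) and 78.8% ± 0.631 (SD, n = 3) in old islets (exact two-sided permutation p 0.486), where the smallest p that 4 against 3 libraries allow is 0.0286. With reads pooled over the same sites, the high-fat libraries differed by -0.610 points in young islets (exact permutation p 0.0571) and by -0.00596 points in old islets (exact permutation p 1). The difference of the means that were not pooled was 0.300 points in old islets, and it was 0.0585 without high-fat library 1, 0.0693 without library 2 and 0.708 without library 4 (exact permutation p 0.0667, the smallest that 4 against 2 libraries allow).

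At promoters, G2/M genes had the largest share of well-covered members among the lists: 13 of 32 (40.6%) had at least 10 reads in every library, against 144 of 45232 (0.318%) of all genes. Sites covered at least 10 times in every library were few: 6 sites in 2 G2/M promoters averaged 5.65% on the standard and 5.81% on the high-fat diet in young islets (exact permutation p 0.943), and 3 sites in 1 promoter averaged 17.2% and 11.8% in old islets (exact permutation p 0.514). At a coverage of at least 5, 132 sites in 12 G2/M promoters went from 30.05% to 31.8% in young islets (exact permutation p 0.0286, adjusted 0.0762), and 86 sites in 11 promoters went from 33.9% to 32.5% in old islets (exact permutation p 0.0571, adjusted 0.114). In young islets, promoters of cell cycle inhibitors (52.6% to 49.1%) and G1/S genes (1.17% to 2.26%), 2 of each, had the same exact permutation p and adjusted p. Over every covered CpG of 27 G2/M promoters, a sum chosen after seeing the data, the levels were 10.0% and 10.6% in young islets (exact permutation p 0.286) and 10.2% and 10.8% in old islets (exact permutation p 0.686), so the direction in old islets turned. The sum over every covered CpG of the Cdk1 promoter (chromosome 10, 69352438 to 69354438) was 7.71% ± 2.89 (SD, n = 4) on the standard diet and 14.8% ± 3.05 (SD, n = 3) on the high-fat diet in old islets, with an adjusted p of 0.285. By the main rule 0 of 19 young and 0 of 11 old promoters changed with diet in the model, with 0 at an unadjusted p under 0.05 and 0 called by limma. Between ages, 1 of 15 promoters passed: Gm10800 (chromosome 2, 98666801 to 98668801) rose by 1.28 points, from 81.8% ± 1.07 (SD, n = 4) to 83.1% ± 0.758 (SD, n = 4), with an adjusted p of 0.0111. Its coverage, summed over its sites, was 5010 to 9868 reads per library, and limma did not call it. The median over the 632 deeply covered sites was 25 reads per site in a library. The cause of the high depth at Gm10800 was not tested, so its reads may not stem from this promoter alone. The call depended on the libraries: the count was 0 without young standard-diet library 1 or 4 or old standard-diet library 1 or 4, 2 without young library 3 and 4 without old library 2.

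**Figure D4:**
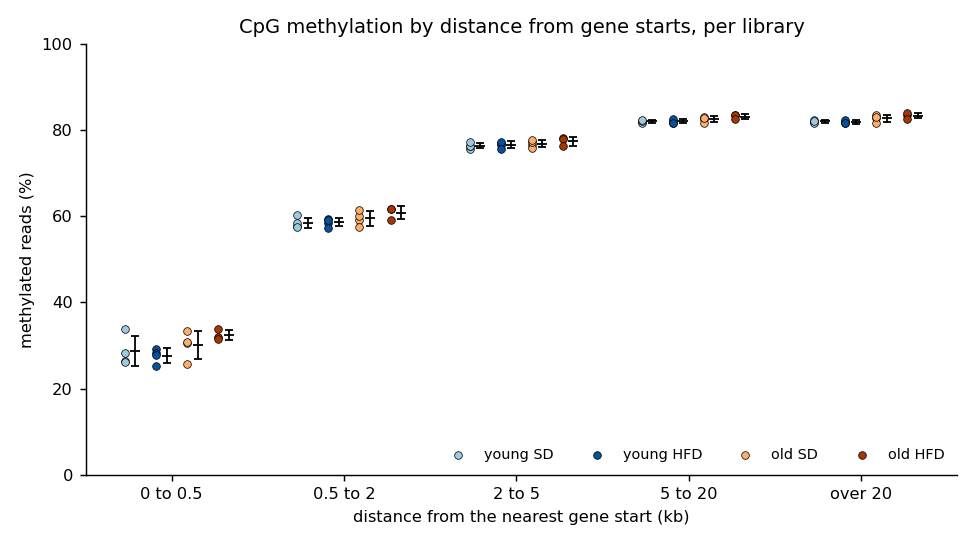
Percent of reads methylated at CpG sites, by distance in kb from the nearest gene start, for each of the 15 methylation libraries; points are libraries and bars show the mean with 1 SD (n = 4 per group, and 3 for old mice on the high-fat diet). Group means within 500 bp of a gene start were 27.6 to 32.4%, and 0 of the distances passed the exact permutation test between groups after adjustment. The smallest exact permutation p before adjustment was 0.114, and the smallest these group sizes allow is 0.0286. A single distance at that smallest p could not have passed after adjustment.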

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

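The tests of other cell types, single samples and handling, and the counts over other splits of the samples, were chosen after the results were seen.

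The diet change differed between ages by the interaction test at 36 genes, and of these 17 are named. The interaction was positive, in log2, for Ppp1r3c (+2.43), Rnd1 (+2.23), Dusp8 (+2.21), Arrdc3 (+1.92), Fam46a (+1.695), Fam84a (+1.66), Nfil3 (+1.54), Hbegf (+1.45), Arid5b (+1.27), Zbtb10 (+1.24), Prdm1 (+1.07) and Msl3l2 (+1.07). It was negative for Hand2 (-2.56), H2afx (-0.78), Anks1 (-0.47), Cacnb3 (-0.40) and Gart (-0.40). Each of the 17 genes lost its call in at least 1 alternative. Of 50 splits drawn, 2 gave as many genes, the real one included, but the other gave 75, more than the real 36, so chance is not taken as excluded for this count. That split kept the old groups as they are and mixed the young ones.

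For gene lists the same difference between ages was called for immediate early genes (adjusted p 9.55e-10, and adjusted p = 0.547 with an estimated correlation), ribosome biogenesis (1.04e-07 and 0.316), unfolded protein response (3.28e-06 and 0.490), heat shock (2.57e-05 and 0.547), Schwann cell (6.37e-05 and 0.490), acinar cell (4.92e-04 and 0.831) and G2/M genes (0.00133 and 0.861), each an adjusted p by camera and then with an estimated correlation, by which 0 of the lists passed. Endothelial genes also passed (adjusted p 0.00676, and adjusted p = 0.734 with an estimated correlation), but not without young high-fat library 2 (adjusted p 0.179). Inflammation genes passed (adjusted p 0.00676, and adjusted p = 0.818 with an estimated correlation), but not without young standard-diet library 1 (adjusted p 0.103). Red blood cell genes passed (adjusted p 0.0208, and adjusted p = 0.734 with an estimated correlation), but not without young standard-diet library 1 (0.0545), young high-fat library 1 (0.114), old standard-diet sample 2-4 (0.0624) or old high-fat sample 1-4 (0.0936). Fatty acid synthesis genes passed (adjusted p 0.0287, and adjusted p = 0.547 with an estimated correlation), but not without young standard-diet library 1 (0.0832), old standard-diet sample 2-4 (0.210) or old high-fat sample 1-4 (0.0670). Interferon response genes passed (adjusted p 0.0291, and adjusted p = 0.861 with an estimated correlation), but not without young standard-diet library 1 (0.619), young high-fat library 1 (0.0539), old standard-diet library 1 (0.173) or 3 (0.192), or old high-fat sample 1-4 (0.113). Calls also ended for red blood cell and fatty acid synthesis genes with a block for replicates (0.0612 and 0.0949) and without both lymphocyte-rich samples (0.194 and 0.419), for red blood cell and G2/M genes without the libraries numbered 4 (0.0590 and 0.0673), and for interferon genes with the lymphocyte covariate (0.472), each an adjusted p. Chance cannot be excluded for the 12 lists, since 13 of 50 splits gave as many and the highest other gave 15.

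The first pattern is the higher G2/M RNA in young islets on the high-fat diet, a median log2 change of +1.13. Among the lists for lymphocytes, macrophages, stromal, endothelial, acinar and ductal cells the highest median change was 0.0436 in log2. This argues against more RNA from these cells, ductal cells apart, as the source. The mean ductal level was 2.18 ± 0.126 on the standard and 2.60 ± 0.451 mean log2 CPM on the high-fat diet (SD, n = 3), with overlap. It was highest, at 3.05, in high-fat library 1, the young library highest in G2/M genes (2.12), so a ductal share stays open. Marker levels cannot tell whether more of any of these cells were dividing. Schwann cell markers had a median change of 0.82 at low levels (S100b at 0.314 ± 0.045 and 0.966 ± 0.295 CPM, SD, n = 3), and because this is closer to the G2/M change than to 0, more RNA from dividing glia and from other dividing islet cells cannot be told apart. Replication of beta cells on the high-fat diet stays open too, as untested, since whole islets were sequenced.

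The second pattern is the more negative diet change of G2/M genes in old islets. With the lymphocyte level as a covariate the list kept its call by camera (adjusted p 1.22e-06), over a range of 4.80e-09 to 0.861 in all alternatives, and its median interaction was -0.91 against -0.84 without it, which argues against a lymphocyte trend as the whole cause. With an estimated correlation the list did not pass with that covariate (adjusted p 0.627) or without it (adjusted p 0.861). Without old standard-diet sample 2-4 the direction turned and the adjusted p was 0.142. That sample was the highest of its group in G2/M genes and in lymphocyte (mean log2 CPM 3.64), acinar (11.5) and stromal (4.34) genes, so other tissue in 1 sample may account for the interaction. An effect of age on the response to the diet stays open, as untested apart from that sample.

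The third pattern is the higher RNA of immediate early, heat shock and unfolded protein response genes in old islets on the high-fat diet. By camera the highest adjusted p of the 3 lists was 7.02e-07 with the acinar level as a covariate and 2.60e-06 with the lymphocyte level. With an estimated correlation the 3 lists did not pass without a covariate (adjusted p 0.404, 0.404 and 0.141), with the acinar level (0.546, 0.546 and 0.299) or with the lymphocyte level (0.531, 0.531 and 0.221). The median log2 changes of 1.01, 1.13 and 0.43 were 1.12, 1.19 and 0.45 with the acinar and 0.96, 1.07 and 0.40 with the lymphocyte level, and by fry the unfolded protein response list passed with each (adjusted p 0.0159 and 0.0174). The changes were thus of similar size with each covariate, which argues against either trend as the whole cause. Within groups, samples higher in immediate early genes were also higher in heat shock genes over 12 samples (Pearson r 0.706 and Spearman rho 0.797, permutation p 0.00540 for each, adjusted permutation p 0.0216 over the 4 relations computed). Without young standard-diet library 1 and old standard-diet library 3, the samples farthest from the median, r was 0.679. Stress on the islets between dissection and lysis may therefore contribute, and an effect of the diet on old islets stays open beside it, as untested. Myc, which also rose in old islets on the high-fat diet, is in none of the 3 lists. Whether such stress bears on its rise was not tested.

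For comparisons of 3 against 3 samples, the 10 splits are too few for a share under 0.05. In young islets edgeR called 5 genes with 0 as the highest other, DESeq2 707 with 44, and camera 14 lists with 19. In old islets edgeR called 758 with 124 as the highest other, DESeq2 2006 with 298, and camera 13 lists with 15. For age, edgeR called 5378 with 0 as the highest other, and camera 14 lists with 17. At least as many lists as in the real split were called in 6 of the 10 splits for young islets. The same held for 4 in old islets and 3 for age, the real split included. Chance therefore cannot be excluded for these list counts. For CpG sites, and for promoters except by age, the real count was 0, which each of the 35 splits (100 for the interaction) reaches whatever the data hold, so these splits say nothing about chance. The highest other count was 0 for CpG sites in each comparison, and for promoters 1 for the diet in young islets, 1 in old islets and 2 for the interaction. With every covered CpG the real counts were 0 as well, and the highest others were 0 in young islets, 1 in old islets, 0 for age and 3 for the interaction. For promoters by age the real count was 1, and 6 of 35 splits gave as many, with 2 as the highest other, so chance cannot be excluded.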

How the results depend on the processing

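The covariate of lymphocyte genes, the treatments of near-identical and lymphocyte-rich samples, the sum over every covered CpG and the sets called by DESeq2 or by the authors' deposited table were chosen after seeing the data. The number of genes called was unstable for the diet and stable for age, where each alternative stayed within 1.5 times of 5378. For young islets edgeR called 5 genes, 19 without a filter, 46 with all RNA libraries in 1 fit, 0 with the lymphocyte covariate, 0 in each fit that left out a library, and DESeq2 called 707. For old islets it called 758 genes, 1261 with at least 1 CPM, 1441 in 1 fit, 1382 with an acinar covariate, 2 with the lymphocyte covariate, 2983 with near-identical libraries apart, 1187 without lymphocyte-rich samples, 0 to 468 without each sample in turn, and DESeq2 called 2006. For the interaction it called 36 genes, 385 with near-identical libraries apart, 0 without lymphocyte-rich samples, 9 with the lymphocyte covariate, 0 to 69 without each sample in turn, and DESeq2 called 448. With near-identical libraries apart, each such pair enters as 2 samples, so the larger counts of that setting cannot be read as more evidence. Fits that leave out a sample have fewer samples, and for the other changes the cause was not tested.

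Nothing in the labels says that equal replicate numbers mark a pair. Correlations across genes of RNA profiles, after removing group means, were -0.207 to 0.111 for equal numbers and -0.252 to 0.267 for unequal numbers. With 3 samples per group these values cannot decide whether the samples were paired. With a block for the replicate numbers, taken as the first number of a summed sample, the counts were 0 genes in young islets, 0 in old islets, 0 for the interaction and 0 promoters for age.

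With an estimated correlation, 0 of 14 lists in young islets, 0 of 13 in old islets and 0 of 12 for the interaction kept their call, and with fry 0, 4 and 0 were called. By age 0 of 14 lists kept their call with an estimated correlation and 15 were called with fry. The acinar list in young islets (adjusted p 0.00537) ran from 4.25e-06 to 0.888 without each library in turn and turned in direction at 0.888 and with its own level as a covariate (0.0719), which removes it by construction, as in old islets (0.563). The macrophage list in young islets turned with the lymphocyte covariate (adjusted p 0.00442). The G2/M list for the interaction ran from 4.80e-09 to 0.142 without each sample and turned at 0.142 without old standard-diet sample 2-4 and at 0.142 without both lymphocyte-rich samples. Mki67 in old islets turned to +1.17 without these and passed (adjusted p 0.0380). For the set of genes risen in young islets, fry gave p 0.454 in old islets, 0.190 to 0.688 without each sample, 0.00149 for the genes called by DESeq2 and 0.00173 for those of the authors' deposited table. For the fallen set the fry p was 0.0598, 0.0326 to 0.177 without each sample, 0.00829 with near-identical libraries apart, 0.00500 without lymphocyte-rich samples, 0.00433 in 1 fit, 0.0257 with the acinar and 0.00348 with the lymphocyte covariate, 0.0107 for the set of the authors' deposited table, and 0.0454 by camera. Promoters called with the diet in young islets numbered 0, and 0 to 1 without each library. For age 1 promoter was called, 0 to 4 without each library, 0 at a coverage of 5, 0 with limma, 0 in a window of 5000 bp upstream to 1000 bp downstream and 0 with every covered CpG. The cause of these changes was not tested.

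Over the alternatives fixed beforehand, values of named genes stayed on the same side of the threshold 7333 times, lost the call 746 times and gained it 237 times. The 7333 include any changes of sign where neither fit made a call. Of called named genes, 92 of 120 for age and 0 of 67 in old islets, 0 of 5 in young islets and 0 of 17 for the interaction kept their call in each alternative run. At the depth and number of the young libraries, the site model recovered 45 of 200 simulated sites at a logit shift of 1 and 179 of 200 at a shift of 2. How far depth, spread or library number sets this limit was not tested. Kallisto counts and Myc motifs were not run.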

Other observations

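In old islets on the high-fat diet, the clock repressors Nfil3 and Nr1d1 rose by 1.27 (SE 0.16, adjusted p 0.0216) and 0.74 (SE 0.10, adjusted p 0.0247) log2, while Hlf and Tef, clock-driven transcription factors, fell by 0.68 (SE 0.08, adjusted p 0.0216) and 0.31 (SE 0.06, adjusted p 0.0414). The list of 15 clock genes was not called (adjusted p 0.311). In young islets Arntl, a core activator of the clock, differed by -0.79 (SE 0.10, adjusted p 0.0819). With age on the standard diet 8 of 15 clock genes rose and 2 fell (list adjusted p 0.00521, and adjusted p = 0.428 with an estimated correlation), among them Tef, risen by 0.89 (SE 0.08). The hour at which islets were taken is not given in the labels.

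The list of 13 genes that write, read or erase DNA methylation was not called by camera in any comparison (adjusted p 0.183 in young and 0.933 in old islets, 0.248 for the interaction and 0.0990 for age). By fry it was lower with age (adjusted p 0.00149, and adjusted p = 0.428 by camera with an estimated correlation) and not called in the other comparisons (0.0670 in young islets), and single members passed. Dnmt3a, a DNA methyltransferase gene, fell by 0.32 (SE 0.05, adjusted p 0.0293) in old islets on the high-fat diet and differed by -0.31 (SE 0.09, adjusted p 0.176) in young ones. Gadd45g and Gadd45a, stress genes also linked to DNA demethylation, rose by 0.94 (SE 0.17) and 0.58 (SE 0.12) in old islets. Tet1, which oxidises methylated cytosine, differed by -0.66 (SE 0.12, adjusted p 0.109) with the diet in young islets and fell by 0.61 (SE 0.12, adjusted p 0.00289) with age. The calls for Nfil3, Nr1d1, Hlf, Tef, Dnmt3a, Gadd45g and Gadd45a in old islets each ended when some single samples were left out.

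With age, secretory granule genes were lower in old islets: 11 of 19 fell and 0 rose (list adjusted p 6.04e-05, and adjusted p = 0.428 with an estimated correlation), among them the vesicle protein gene Vamp2, fallen by 0.71, and Chgb, the chromogranin B gene, fallen by 0.66. Of 8 alpha cell genes 5 fell and 0 rose by edgeR (list adjusted p 0.00653, and adjusted p = 0.428 with an estimated correlation). In the same comparison all 23 acinar genes were higher (median log2 change +1.30, list adjusted p 0.0277, and adjusted p = 0.833 with an estimated correlation, and 0.247 without old standard-diet sample 2-4 or 0.106 without young standard-diet library 2, with a median of +0.62 without sample 2-4) and the ductal level was higher by 0.80 mean log2 CPM. All these values share the limit that the ages were processed apart.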
